A study of Mus musculus with 73 samples.

How the data were processed

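RNA of mouse tumors and normal tissues was measured on 2-colour cDNA microarrays of 9596 features, 73 arrays in all. On 35 arrays 1 tissue (Cy3) was hybridised against a universal reference RNA (Cy5), with normal and tumor samples of prostate, seminal vesicle, mammary gland and lung. On the other 38 arrays a mammary tumor (Cy5) was hybridised directly against normal mammary gland (Cy3), in 8 mouse models. Dyes were fixed within each set and no swapped arrays are labelled, so a dye bias does not cancel on the direct arrays.

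The deposited values are log2 ratios made by the authors, 1 per feature and array. The labels state neither the base nor the direction of the ratio, and both were checked on the values. Applied to the values read as log2, the interaction rule in the series text gave 2633 of 9532 tested features, where that text states 2638. Read as natural logarithms the values gave 3764 features, and as logarithms to base 10 they gave 4168. In normal lung all 11 measured markers of lung epithelium were higher than in the mean of the other 3 normal tissues, and in normal mammary gland all 17 adipocyte markers were. In normal prostate 7 of 10 prostate secretory genes were higher, and in normal seminal vesicle the 1 measured secretory gene was higher. The reference ratios were read as sample over reference. Across 5755 genes, which are not independent replicates, the mean of the direct C3(1) Tag arrays had a Pearson r of 0.498 and a Spearman rho of 0.379 with the mammary tumor change of the reference arrays, and the direct ratios were read as tumor over normal. The reference arrays were centred by the authors, with medians from -0.05 to 0.01. The direct arrays were not centred over these features, with medians from -0.42 to 0.66. Image analysis, background correction and the filter behind missing values are not stated. The number of arrays limits the precision. The files hold ratios without intensities, so the limit set by weak signals could not be assessed.

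Features were paired with genes through the probe table of the series, and symbols were updated by gene ID against the mouse RefSeq annotation of GRCm38.p6. Of the features, 7486 carry 1 symbol (7395 matched by gene ID and 91 kept their deposited symbol), 483 carry several and 1627 carry none. Features with several symbols or none were left out at gene level. Features of 1 gene were averaged on each array, which gave 6777 genes on the reference arrays and 5768 on the direct arrays. Of these, 631 genes have several features. In prostate 278 genes had at least 2 features that passed the test on their own, and in 45 of them the features went opposite ways. The numbers were 40 of 130 in seminal vesicle, 5 of 128 in mammary gland and 7 of 129 in lung. 8 features hold no value on any array, and 1648 hold none on the direct arrays.

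All tests across genes used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8). The reference arrays were fitted with 8 group means and the direct arrays with 8 model means. A gene was tested when each group compared held at least 3 values, and it passed at a Benjamini-Hochberg adjusted p under 0.05. The difference of the tumor change among the 4 sites was tested with a moderated F on 3 contrasts. Genes shared by the 3 epithelial tumors passed in mammary gland, lung and prostate with at least a 2-fold change in 1 direction. Genes specific to 1 site passed at 2-fold there and not in the other epithelial sites, and their change also had to differ from the mean of the others at an adjusted p under 0.05. Each direct model was tested against 0, and the spread of normal mammary gland does not enter that test. Prostate and seminal vesicle come from C57BL/6 and mammary gland and lung from FVB, so strain cannot be told apart from location between these 2 pairs. No label says whether samples came from separate animals, and p-values measure the spread between samples.

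Gene lists, 29 in number, were fixed before the data were examined. Those with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. Both used Benjamini-Hochberg adjustment within a comparison. The seminal vesicle secretory list (1 measured gene) and the erythroid list (2 measured genes) were too small to test. A score of the shared genes, the mean of those that rose minus the mean of those that fell, was taken on each direct array and compared with exact two-sided permutation tests.

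The genes named were taken by a rule fixed before the data were examined. For each tumor against normal comparison of the reference arrays they were the 8 largest rises and falls among passing genes whose tumor arrays all lay on 1 side of all normal arrays. Up to 3 genes with the smallest p from each list that passed camera were added. For the shared genes the rule took the 10 largest rises and falls by the smallest of the 3 changes. For site-specific genes and for contrasts between sites or models it took the 6 largest each way. For each direct model it took the 3 largest each way with 1 sign on all arrays. Rb1, Brca1, Myc, Ccnd1, Mki67 and Top2a were named throughout. Trp53, Erbb2, Hras, Cdkn2a and Pcna were on the same list and are not measured. Clone names were skipped, 5 in all. Genes named outside the rule are marked as such in the text.

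The pipeline was tested on simulated data with known changed genes in each comparison. A log2 change of 1 was recovered for 95.5% of changed genes in prostate and seminal vesicle, 91.0% in mammary gland and 94.0% in lung. In the direct comparisons between 80.6% and 95.5% were recovered at that size. At a log2 change of 0.5 the shares were 59.7% in prostate, 64.2% in seminal vesicle, 56.7% in mammary gland and 58.2% in lung, and from 14.9% to 49.3% in the direct comparisons. Unchanged genes made up between 1.41% and 7.74% of the calls. The simulated noise was drawn for each gene alone, without correlation between genes or effects of array runs. Few genes were changed, with 178 calls in prostate where the data gave 4157, so these shares do not carry over to the real calls.

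Alternatives covered scaling (median centring, quantile normalization), missing values, features in place of genes, the groups that enter the fit, the variance model, array weights, replicate and array number blocks, the study's own rule, and each array left out in turn. Array database numbers in the labels fell into 6 runs of neighbouring numbers (gaps of at most 20) on the reference arrays and 18 on the direct arrays. Runs were fitted as a random block and, on the reference arrays, as a fixed factor. Values within run 1 (for prostate 3 normal arrays and 1 tumor array, with the spread shared with mammary and lung arrays of that run) and the mean of the skeletal muscle list as a covariate were added after the data were seen. So were the score without C3(1) Tag, the score without the adipocyte list, its rising and falling parts on centred arrays, and the shared genes in seminal vesicle under other scalings and with runs as a factor. Figures were drawn with matplotlib 3.10.9. No array was left out.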

Results

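The 73 arrays fall into 16 groups. Prostate and seminal vesicle samples are C57BL/6, with tumors of TRAMP mice, in which a probasin promoter drives the SV40 T/t-antigen. There were 4 normal and 5 tumor arrays of prostate, and 4 normal and 6 tumor arrays of seminal vesicle. Mammary gland and lung samples are FVB, with tumors of C3(1) and CC10 promoter SV40 T/t-antigen mice, and 4 normal and 4 tumor arrays each. The SV40 large T antigen binds and inactivates the tumor suppressors p53 and Rb. The 38 direct mammary arrays comprise p53 null transplants (n = 5, Balb/c), p53 floxed WAP-cre (n = 4, label p53fp/fp;WAP-cre) and Brca1 floxed MMTV-cre p53 tumors (n = 5, label Brca1 Co/Co;MMTV-cre;p53), the latter both C57BL6/129sv. The FVB models among them are C3(1) Tag (n = 5, label C3(1)/SV40 T/t-antigen), MMTV-her2/neu (n = 5), MMTV-myc (n = 4), MMTV-ras (n = 5) and MMTV-PyMT (n = 5). Between 9244 and 9572 features held a value on the reference arrays, and between 7042 and 7934 on the direct arrays. Changes are log2 tumor minus normal with the standard error of the limma fit. Each gene named by size in a tumor against normal comparison of 1 site on the reference arrays had all tumor arrays on 1 side of all normal arrays. Shared and site-specific genes were named without that condition.

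The first comparison asked which genes distinguish prostate tumors from normal prostate. Genes of cell division rose. Of 33 measured mitosis genes 31 rose, with Ccna2, an S and G2 phase cyclin, at 4.06 ± 0.21, Top2a at 3.71 ± 0.19 and the motor protein Kif4 at 2.88 ± 0.16. All 27 DNA replication genes rose, including Mcm5 of the replicative helicase at 3.19 ± 0.19, Dut at 2.86 ± 0.18 and Prim1 at 2.43 ± 0.15. Of 13 DNA repair genes 9 rose (Brca1 3.11 ± 0.16, Rad21 2.74 ± 0.16, Blm 1.48 ± 0.14), and of 12 chromatin genes 9 rose (Hmgn2 3.30 ± 0.19, Hells 2.46 ± 0.19, Cbx5 1.99 ± 0.15). In camera these lists passed, and with an estimated correlation the adjusted p was 0.0255 for mitosis, 0.0585 for replication, 0.105 for repair and 0.0677 for chromatin. Neuroendocrine cell markers also rose, 8 of 11 (adjusted p = 0.037 with an estimated correlation). Among them were the secretory granule protein Scg3 at 2.26 ± 0.16 and the neuronal genes Gap43 at 2.68 ± 0.16 and Nsg1 at 2.66 ± 0.18. Further large rises were in Tubb5 (4.37 ± 0.17), Pclaf (4.12 ± 0.17), the neuronal RNA-binding protein Elavl4 (3.93 ± 0.19), Esco2 (3.62 ± 0.16), Marcksl1 (3.55 ± 0.19) and Nusap1 (3.43 ± 0.24). Mki67 rose by 2.61 ± 0.26 and Rb1 by 1.09 ± 0.16. Myc stood at 0.21 ± 0.23 and did not pass.

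Epithelial genes fell in prostate tumors. Of 12 keratin and junction genes 10 fell, among them Krt8 at -3.23 ± 0.18, Krt19 at -2.58 ± 0.20 and the epithelial transcription factor Ehf at -3.52 ± 0.30 (adjusted p = 0.0677 with an estimated correlation). Of 13 basal and squamous markers 11 fell (Krt15 -1.78 ± 0.13, Krt17 -1.93 ± 0.23, Krt6a -1.30 ± 0.13, adjusted p = 0.119 with an estimated correlation). Dcpp3, a demilune cell and parotid protein gene, fell most, at -7.26 ± 0.14. Skeletal muscle markers fell, 14 of 14, with myoglobin Mb at -5.70 ± 0.47, Eno3 at -4.09 ± 0.36 and the calcium pump Atp2a1 at -3.31 ± 0.31 (adjusted p = 0.229 with an estimated correlation). Tnnc2 (-5.76 ± 0.76), Mylpf (-5.49 ± 0.52), Tnni2 (-4.91 ± 0.62) and Myh1 (-4.80 ± 0.55), all of fast muscle fibres, were among the largest falls. The mean log2 ratio of this list was 3.96 ± 0.37 (SD, n = 4) in normal prostate, -0.11 ± 0.08 (n = 5) in prostate tumors and -0.07 ± 0.09 (n = 4) in normal seminal vesicle. Moving with it, 8 of 9 smooth muscle genes fell (Tpm2 -4.84 ± 0.38, Myl9 -2.30 ± 0.20, Tagln -2.27 ± 0.23), as did 14 of 17 adipocyte markers (Car3 -3.84 ± 0.34, Slc2a4 -2.89 ± 0.22, Plin4 -2.18 ± 0.21) and 15 of 20 respiratory chain genes (Ndufv1 -1.52 ± 0.13, Cox6c -0.92 ± 0.13, Ndufs7 -0.90 ± 0.10). With an estimated correlation the adjusted p was 0.16 for smooth muscle, 0.242 for adipocytes and 0.33 for the respiratory chain. Fibroblast and matrix genes fell in 8 of 16 cases (Ogn -3.44 ± 0.31, Gsn -3.19 ± 0.24, Lum -1.73 ± 0.28, adjusted p = 0.429 with an estimated correlation). Secretory pathway genes of the endoplasmic reticulum fell in 12 of 20 (Dnajc3 -1.80 ± 0.20, Herpud1 -1.40 ± 0.13, Edem1 -1.14 ± 0.11, adjusted p = 0.266 with an estimated correlation). Of the airway and alveolar markers 6 of 11 fell (Cyp2f2 -4.33 ± 0.38, Aqp5 -2.32 ± 0.19, Abca3 -1.10 ± 0.08, adjusted p = 0.241 with an estimated correlation). Ribosomal protein genes rose, 16 of 21 (Rps6 1.06 ± 0.16, Rpl35 1.02 ± 0.20, Rps15 0.98 ± 0.19, adjusted p = 0.449 with an estimated correlation), and 9 of 21 under quantile normalization. Mup9 fell by 4.89 ± 0.42 and cyclin D1, Ccnd1, by 1.25 ± 0.34. All these list counts were the same when adjusted over the list alone, except 16 falls for the respiratory chain and 19 rises for ribosomal proteins. In all, 4157 of 6767 genes passed, 1976 higher and 2181 lower, and 1159 of them changed at least 2-fold. Within array run 1, which holds 3 normal arrays and 1 tumor array, 3263 genes passed with a spread taken from other arrays of that run. With the skeletal muscle mean as a covariate 1840 passed, while the median standard error rose from 0.127 to 0.256. The slope of that covariate came mostly from mammary arrays, where the muscle mean varied most within groups. Under that covariate 4 adipocyte markers fell (mean change -1.33 before, -0.53 after), 5 smooth muscle genes (-1.89 and -0.81), 2 respiratory chain genes (-0.49 and -0.11), 6 basal markers (-0.74 and -0.83) and 5 matrix genes (-0.885 and -0.999), and 0 ribosomal protein genes rose (0.56 and 0.24).

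Seminal vesicle tumors of TRAMP mice were compared with normal seminal vesicle. Matrix genes rose in 13 of 16 cases, led by the collagens Col1a2 at 2.74 ± 0.25 and Col1a1 at 2.67 ± 0.24 with the proteoglycan Bgn at 1.78 ± 0.19. Sparc rose by 2.46 ± 0.26. Replication genes rose in 22 of 27 cases (Mcm5 1.77 ± 0.18, Rrm1 1.48 ± 0.15, Mcm3 1.21 ± 0.13) and mitosis genes in 27 of 33 (Top2a 1.61 ± 0.18, Anln 1.40 ± 0.16, Kif20a 1.18 ± 0.14). Chromatin genes rose in 9 of 12 (Hmgn2 1.56 ± 0.18, Hells 1.37 ± 0.18, Hmgb1 1.20 ± 0.16). For each of these 4 lists the adjusted p was 0.21 with an estimated correlation. Glycolysis and hypoxia genes rose in 6 of 11 cases (Pgk1 0.98 ± 0.16, Ldha 0.91 ± 0.17, Hk1 0.63 ± 0.09), with an adjusted p of 0.531 with an estimated correlation. The mean change of that list turned from 0.44 to -0.07 under quantile normalization, with 1 gene higher. The same scaling left 7 mitosis genes (mean change 0.70 before, 0.28 after), 16 replication genes (0.80 and 0.49) and 4 chromatin genes (0.66 and 0.43) that rose. Adjusted over the list alone, 11 chromatin and 7 glycolysis genes rose and 1 matrix gene fell, with the other counts the same. The acute phase and secreted proteins Lcn2 (2.89 ± 0.36) and Clu (2.70 ± 0.32), the cartilage genes Mia (2.53 ± 0.37) and Col2a1 (2.47 ± 0.26), and Ly6c1 (2.50 ± 0.24) were among the largest rises. Cyclin D1, Ccnd1, rose by 1.22 ± 0.33. Orm1 (-2.64 ± 0.34), Orm2 (-2.44 ± 0.28), the secretory protein Spink1 (-2.17 ± 0.28), Calb1 (-1.99 ± 0.25), Lst1 (-1.99 ± 0.27), Pnliprp1 (-1.99 ± 0.23), Rasa4 (-1.93 ± 0.21) and Fndc5 (-1.93 ± 0.25) fell most. Mki67 rose by 0.80 ± 0.25, a call that was lost without normal array 2 (0.65) or 3 (0.67). Brca1 (-0.06 ± 0.15), Myc (-0.31 ± 0.23) and Rb1 (0.32 ± 0.16) did not pass. Of 6767 genes 2943 passed, 1579 higher and 1364 lower, and 225 changed at least 2-fold. All normal arrays lie in array run 3 and all tumor arrays in runs 4 to 6, so no run holds both groups. With runs as a fixed factor 884 genes passed and the median standard error rose from 0.123 to 0.296. Besides the 4 normal arrays, run 3 holds only 1 mammary tumor array, and runs 4 and 5 hold only seminal vesicle tumors. The change in that fit thus rests on this 1 mammary array and the 2 seminal vesicle tumors of run 6. After median centring 2907 passed, 1391 higher and 1516 lower, and under quantile normalization 1629, 764 higher and 865 lower, so the direction of the excess depends on scaling.

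Prostate and seminal vesicle tumors arise in the same mouse model, TRAMP, and their tumor changes were compared directly. In this contrast positive values mean a larger rise, or a smaller fall, in prostate. The largest differences upward were those of the neuronal RNA-binding protein Elavl4 (3.91 ± 0.26), the microtubule protein Dcx (3.86 ± 0.31), the fatty acid binding protein Fabp5 (3.81 ± 0.34), the transcription factor Sox11 (3.78 ± 0.23), Esco2 (3.44 ± 0.22) and the kinase Pak3 (3.44 ± 0.26). Of 11 neuroendocrine markers 9 were higher (adjusted p = 0.0135 with an estimated correlation), and of 33 mitosis genes 31 were (0.0386 as the same adjusted p). In 19 of 27 replication genes, 8 of 12 chromatin genes, 7 of 13 repair genes and 9 of 21 ribosomal protein genes the change was larger in prostate. Their adjusted p with an estimated correlation were 0.206, 0.292, 0.288 and 0.532. Matrix genes went the other way in 15 of 16 cases, epithelial genes in 9 of 12 and basal markers in 9 of 13. For these the adjusted p with an estimated correlation was 0.0899, 0.0386 and 0.046. The skeletal muscle genes differed in 14 of 14 cases (Mb -6.06 ± 0.65, Mylpf -5.73 ± 0.72, Tnnc2 -6.14 ± 1.06; adjusted p = 0.206 with an estimated correlation) and the smooth muscle genes in 8 of 9 (Tpm2 -5.48 ± 0.53; adjusted p = 0.0899 with an estimated correlation). Respiratory chain genes were lower in 14 of 20 cases, adipocyte markers in 9 of 17, airway markers in 6 of 11 and interferon-stimulated genes in 8 of 15. With an estimated correlation their adjusted p was 0.299, 0.329, 0.206 and 0.414. When adjusted over the list alone, 10 epithelial, 10 basal and 7 ribosomal protein genes and 3 repair genes in the lower direction passed, and the other counts were the same. Dcpp3 (-6.71 ± 0.19) and Mia (-6.29 ± 0.54) were lowest. Brca1 (3.18 ± 0.22), Top2a (2.10 ± 0.26), Mki67 (1.81 ± 0.37) and Rb1 (0.77 ± 0.22) were higher, Ccnd1 lower (-2.48 ± 0.47), and Myc did not pass (0.52 ± 0.33). Of 6759 genes 3156 passed, 1526 higher and 1630 lower. With array runs as a fixed factor 1797 passed, and with the skeletal muscle mean as a covariate 1535. The run factor links normal seminal vesicle to other runs through 1 mammary tumor array only. Under quantile normalization 9 respiratory chain genes were lower.

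**Figure D1:**
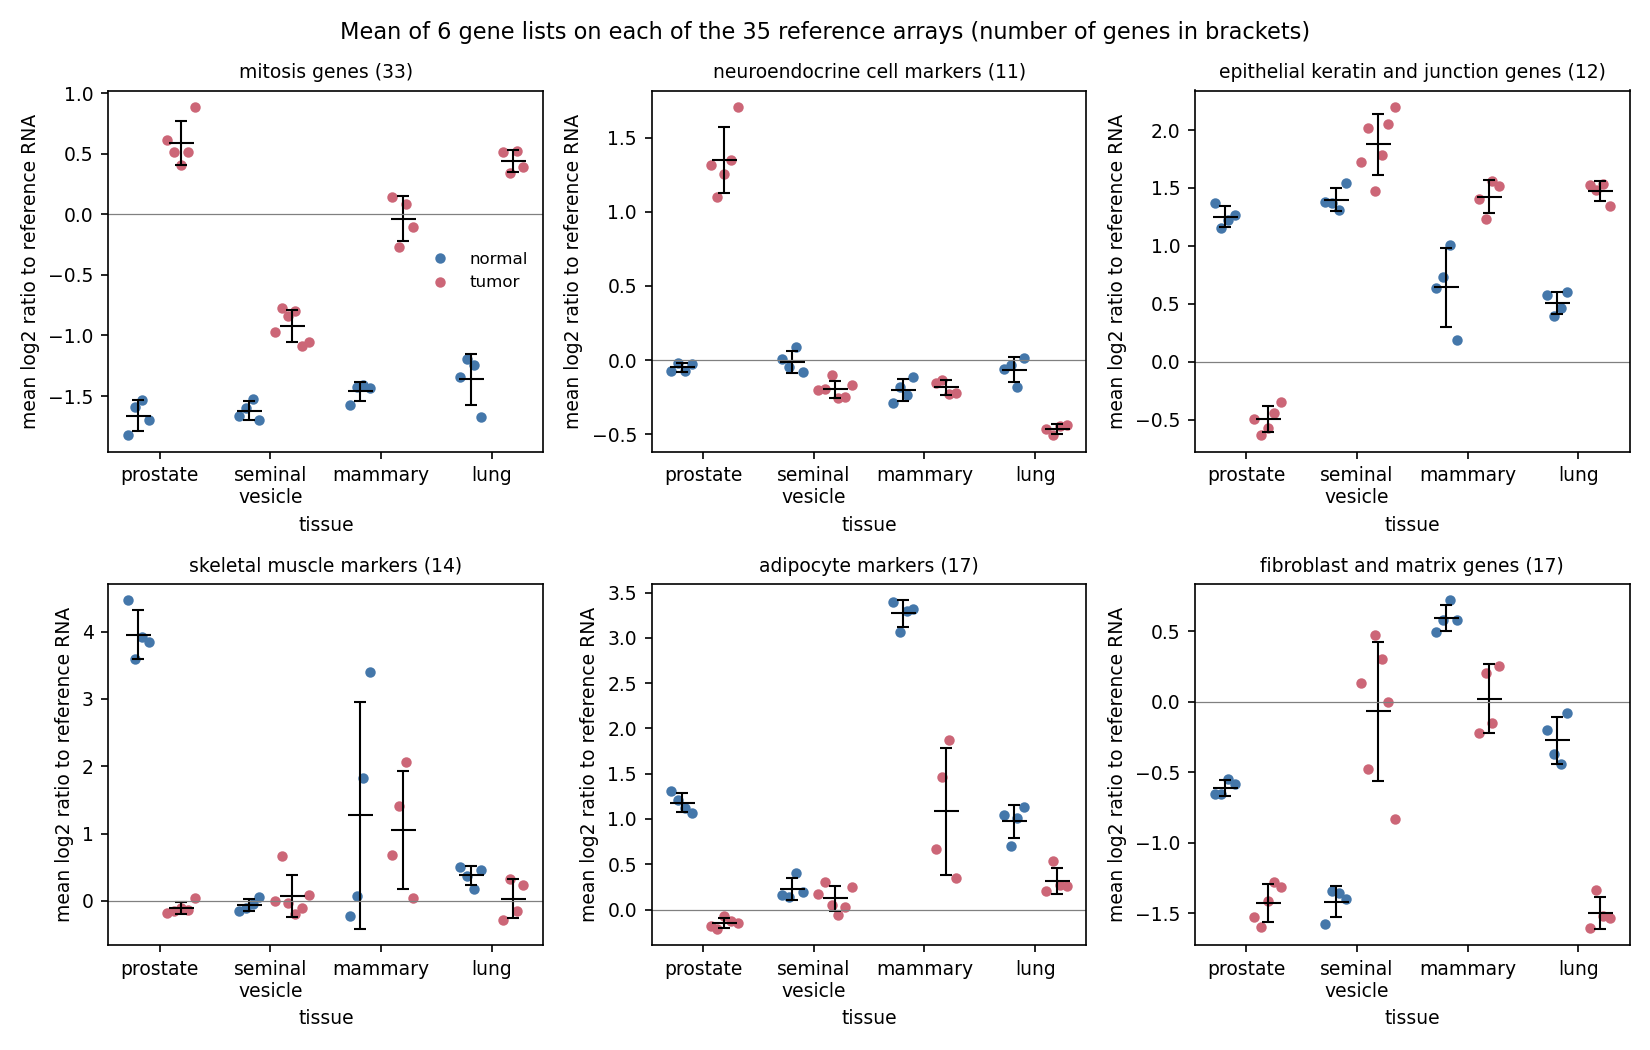
Mean log2 ratio to the reference RNA of 6 gene lists on each of the 35 reference arrays, by tissue, with normal arrays in blue and tumor arrays in red; black bars give the group mean and SD. Neuroendocrine means lay between 1.10 and 1.71 in the 5 prostate tumors, and skeletal muscle means between 3.59 and 4.46 in the 4 normal prostates.

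In mammary gland, tumors of C3(1) Tag mice were compared with normal gland. Mitosis genes rose in 31 of 33 cases (Anln, a cytokinesis protein, 3.33 ± 0.18, Ccna2 2.77 ± 0.22, Nek2 2.07 ± 0.16) and replication genes in 22 of 27 (Pola1 2.57 ± 0.17, Prim1 1.84 ± 0.16, Slbp 1.71 ± 0.17). Repair genes rose in 11 of 13 cases (Brca1 1.90 ± 0.17, Rad21 1.48 ± 0.17, Brca2 0.71 ± 0.12) and chromatin genes in 7 of 12 (Hells 2.35 ± 0.20, Smarca5 1.43 ± 0.16, Suz12 1.14 ± 0.20). These 4 lists also passed with an estimated correlation. Epithelial genes rose in 8 of 12 (Epcam 2.32 ± 0.30, Cdh1 1.54 ± 0.31, Cldn7 1.20 ± 0.19, adjusted p = 0.101 with an estimated correlation). Adipocyte markers fell in 16 of 17 cases, with the adipokine Adipoq at -2.88 ± 0.22, Plin4 at -2.64 ± 0.22 and Lipe at -2.22 ± 0.17. All 20 respiratory chain genes fell (Sdhb -1.23 ± 0.15, Cox6c -1.09 ± 0.14, Atp5g3 -0.95 ± 0.11). Milk and luminal genes fell in 10 of 16 (Glycam1 -4.03 ± 0.24, the kappa casein Csn3 -2.95 ± 0.35, Btn1a1 -2.50 ± 0.14), and T cell markers in 7 of 10 (Cd3g -1.20 ± 0.14, Cd8a -1.06 ± 0.11, Cd5 -0.88 ± 0.13). These 4 lists passed with an estimated correlation too. Under quantile normalization 6 luminal genes fell, with a mean change of -0.68 against -1.05. B cell markers fell in 4 of 5 (Cd79b -1.47 ± 0.22, Cd79a -1.31 ± 0.17, Cd22 -0.58 ± 0.11), MHC class II genes in 5 of 6 (H2-Aa -1.68 ± 0.37, H2-DMa -0.57 ± 0.13, Ciita -0.44 ± 0.08) and endothelial markers in 9 of 13 (Cdh5 -1.45 ± 0.25, Egfl7 -1.41 ± 0.19, Kdr -1.10 ± 0.16). Their adjusted p with an estimated correlation was 0.0827, 0.0875 and 0.149, and under quantile normalization 3 MHC class II genes fell (mean change -0.52 against -0.84). Ribosomal protein genes fell in 15 of 21 cases (Rplp1 -1.08 ± 0.24, Rpl13a -0.99 ± 0.21, Rps14 -0.83 ± 0.19, adjusted p = 0.472 with an estimated correlation). Matrix genes fell in 9 of 17 and rose in 2 (Gsn -2.60 ± 0.25, Mmp2 -0.89 ± 0.20, Fbln2 1.10 ± 0.22, adjusted p = 0.537 with an estimated correlation). Immediate early genes rose in 4 of 11 (Ccn1 1.23 ± 0.43, Junb 0.66 ± 0.17, Socs3 0.66 ± 0.14, adjusted p = 0.483 with an estimated correlation), with the call of Ccn1 lost without normal array 1 (1.07) or 3 (1.19).

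The largest other rises in mammary tumors were Nt5e (2.77 ± 0.31), Sgo1 (2.51 ± 0.20), the decoy receptor Tnfrsf11b (2.42 ± 0.15), the serpin Serpinb5 (2.41 ± 0.30) and Mcm6 (2.41 ± 0.26). Of lipid metabolism, Thrsp (-3.43 ± 0.33) and the desaturase Scd1 (-3.01 ± 0.36) fell, as did Mmd (-2.99 ± 0.18), Rbp4 (-2.96 ± 0.34) and the pyruvate carboxylase Pcx (-2.91 ± 0.18). Top2a rose by 1.83 ± 0.20 and Mki67 by 1.63 ± 0.28, while Rb1 (0.23 ± 0.17), Myc (-0.09 ± 0.25) and Ccnd1 (-0.86 ± 0.36) did not pass. The falls, adjusted over the list alone, came to 16 for ribosomal proteins, 11 for luminal genes, 10 for endothelial markers, 8 for T cell markers and 2 for replication. The rises came to 32 for mitosis, 23 for replication and 9 for epithelial genes. A further epithelial gene fell, and the other counts were the same. The skeletal muscle mean ranged from -0.23 to 3.40 over the 4 normal glands and from 0.05 to 2.07 over the tumors. Of 6771 genes 2485 passed, 1123 higher and 1362 lower, 520 of them at least 2-fold. Within array run 1 (3 normal and 3 tumor arrays) 2132 passed.

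Lung tumors of CC10 Tag mice were compared with normal lung. Mitosis genes rose in 32 of 33 cases (Anln 3.83 ± 0.18, Ccna2 3.26 ± 0.22, Top2a 3.02 ± 0.20) and replication genes in 24 of 27 (Pola1 2.27 ± 0.17, Mcm5 2.23 ± 0.20, Prim1 1.70 ± 0.16). Chromatin genes rose in 10 of 12 (Hells 2.97 ± 0.20, Hmgn2 1.70 ± 0.20, Eed 0.77 ± 0.10), repair genes in 9 of 13 (Brca1 2.41 ± 0.17, Blm 1.33 ± 0.15, Rad21 1.30 ± 0.17) and epithelial genes in 9 of 12 (Krt8 1.58 ± 0.19, Cldn7 1.30 ± 0.19, Elf3 1.12 ± 0.14). These 5 lists passed with an estimated correlation as well. Endothelial markers fell in 12 of 13 cases (Tek, an angiopoietin receptor, -2.15 ± 0.16, Eng -1.47 ± 0.17, Flt1 -1.15 ± 0.12) and p53 target genes in 8 of 13 (Tnfrsf10b -1.38 ± 0.21, Ccng1 -1.29 ± 0.23, Trp53inp1 -1.21 ± 0.22), both also with an estimated correlation. Matrix genes fell in 13 of 17 (Ogn -3.09 ± 0.33, Gsn -2.55 ± 0.25, Bgn -1.86 ± 0.21) and markers of lung epithelium in 8 of 11 (Cbr2 -2.54 ± 0.26, Scgb3a1 -1.18 ± 0.16, the surfactant protein Sftpc -0.96 ± 0.15), with an adjusted p of 0.0866 for each with an estimated correlation. Under quantile normalization 4 lung epithelium markers fell and 2 rose, and the mean change of that list moved from -0.92 to -0.36. MHC class II genes fell in 5 of 6 (Cd74 -1.74 ± 0.35, H2-DMa -0.83 ± 0.13, Ciita -0.35 ± 0.08) and T cell markers in 7 of 10 (Cd3d -0.68 ± 0.14, Gzma -0.68 ± 0.19, Cd8a -0.62 ± 0.11), with an adjusted p of 0.0841 for each with an estimated correlation. Adipocyte markers fell in 6 of 17 (Cd36 -1.58 ± 0.28, Cidea -1.35 ± 0.18, Lipe -0.72 ± 0.17, adjusted p = 0.359 with an estimated correlation). Adjusted over the list alone, 25 replication genes rose, and 14 matrix, 10 p53 target and 7 adipocyte genes fell while 1 p53 target rose; the other counts were the same. Esco2 (3.48 ± 0.17), the spindle motor Kif11 (3.27 ± 0.22), Smc4 (2.72 ± 0.26) and Mki67 (2.63 ± 0.28) rose as well. Hsd11b1 (-3.29 ± 0.36), Selenop (-2.98 ± 0.22), Mup9 (-2.93 ± 0.44), Inmt (-2.73 ± 0.26), Plpp3 (-2.57 ± 0.26) and Ccnd1 (-1.69 ± 0.36) fell. Rb1 (0.23 ± 0.17) and Myc (0.10 ± 0.25) did not pass. Of 6774 genes 2474 passed, 1095 higher and 1379 lower, 480 of them at least 2-fold, and within array run 1 (3 normal and 3 tumor arrays) 2228 passed.

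The study asked which genes changed in all 3 epithelial tumors and which in 1 site alone. In mammary gland, lung and prostate 123 of 6758 genes changed at least 2-fold in the same direction, 91 of them higher and 32 lower. Independent lists of these sizes would share 0.553 and 1.07 genes. Of the 91 rising genes 25 are among the 33 mitosis genes and 13 among the 27 replication genes (Fisher's exact test, adjusted p = 1.74e-40 and 4.93e-17). Chromatin genes (4 of 12, adjusted p = 0.000135) and repair genes (3 of 13, adjusted p = 0.00444) were also over-represented. These tests, and those of the falling genes below, treat genes as independent, so their p-values do not measure the spread between samples. The rises with the largest smallest change were those of Anln, Ccna2, Hells, Kif11, Pola1, Sgo1, Nusap1, Kpna2, Esco2 and Mcm6. Hells, a chromatin remodeler, rose by 2.35 ± 0.20 in mammary, 2.97 ± 0.20 in lung and 2.46 ± 0.19 in prostate tumors. Kpna2, a nuclear import factor, rose by 2.04 ± 0.16, 2.16 ± 0.16 and 2.35 ± 0.15. The 32 falling genes hold 3 of 17 adipocyte markers and 3 of 16 matrix genes (adjusted p = 0.000909 for each). The largest falls were those of Gsn, Mup9, Plpp3, Cav1, Aldh2, Cd36, Mlycd, Lpl, Meox2 and Ptprb. Cav1, the coat protein of caveolae, stood at -2.84 ± 0.23, -2.36 ± 0.23 and -1.89 ± 0.21, and the actin-severing Gsn at -2.60 ± 0.25, -2.55 ± 0.25 and -3.19 ± 0.24. In seminal vesicle tumors 73 of the 91 rising genes rose too, but 38 under quantile normalization and 34 with array runs as a fixed factor. Of the 32 falling genes 1 fell and 11 rose there, with Plpp3 at 1.49 ± 0.24 and Cav1 at 0.88 ± 0.21. Under quantile normalization 7 of these 32 genes rose, and with runs as a factor 1 rose and 3 fell. These alternatives were chosen after the data were seen. In seminal vesicle the run factor links normal arrays to other runs through 1 mammary tumor array only. The study's own rule at feature level gave 153 shared features, where the series text states 153.

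**Figure D2:**
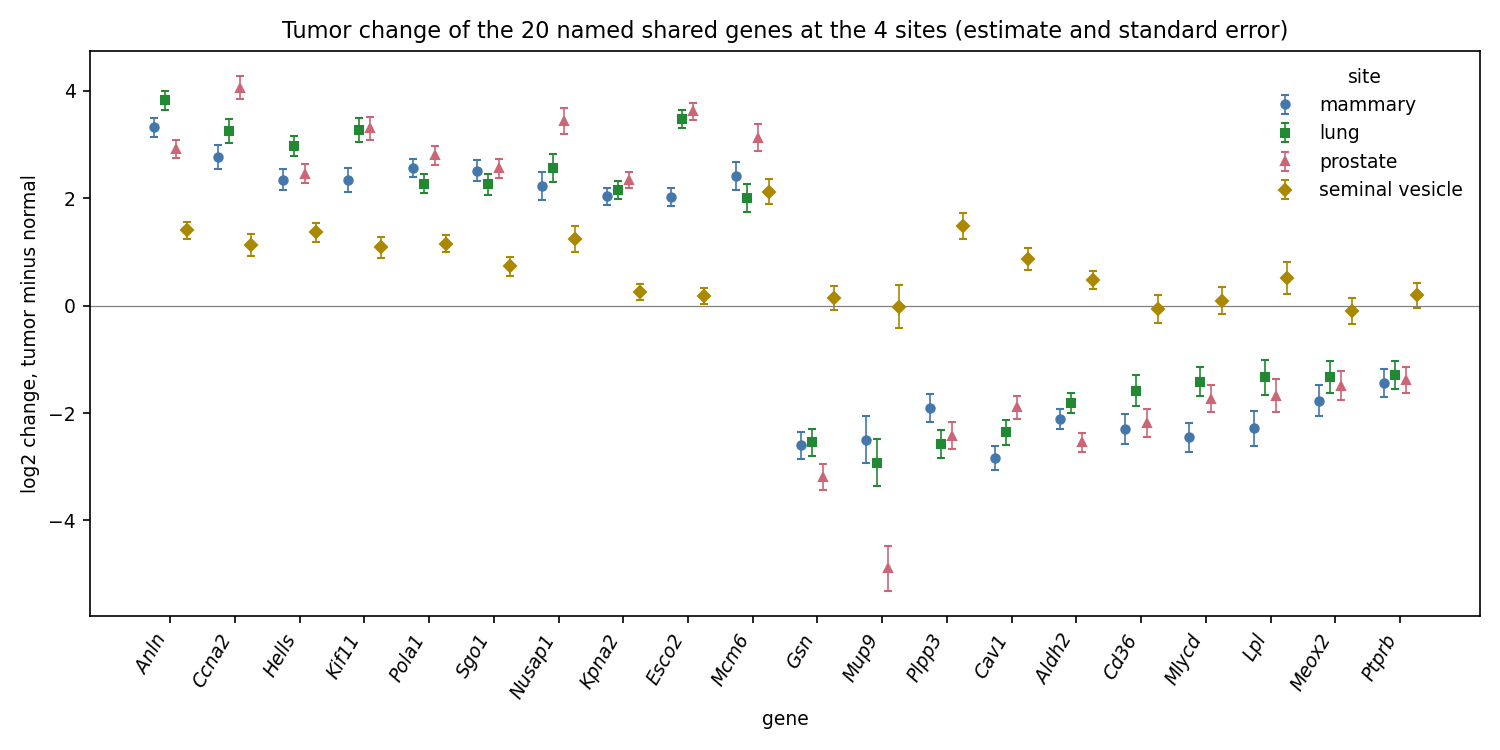
Log2 tumor change (y axis, estimate and standard error of the fit) of the 20 named shared genes (x axis) in mammary gland, lung, prostate and seminal vesicle. In seminal vesicle the rise of Kpna2 (0.25) and Esco2 (0.18) did not pass, and Plpp3, Cav1 and Aldh2 rose while they fell in the other tissues.

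Over the 4 sites together the tumor change differed for 5007 of 6750 genes. Across genes, which are not independent replicates, the changes of mammary gland and lung had a Pearson r of 0.458. Those of prostate had an r of 0.404 with lung and 0.309 with mammary gland, and those of seminal vesicle had an r of 0.110 with mammary gland, 0.133 with lung and 0.184 with prostate. Strain differs between the sites (C57BL/6 for prostate and seminal vesicle, FVB for mammary gland and lung), and between these 2 pairs it cannot be told apart from location. Prostate and seminal vesicle share their strain and still differed at 3156 genes, which strain does not account for. Genes specific to mammary tumors numbered 206, 56 higher and 150 lower. Tnfrsf11b, Serpinb5, Macc1 (2.35 ± 0.26), the transcription factor Foxc1 (2.33 ± 0.25), Nkd2 (2.18 ± 0.24) and Sdc1 (2.15 ± 0.15) led the rises. Glycam1, Csn3, Pcx, Pparg (-2.77 ± 0.24), a regulator of fat cell differentiation, Fasn (-2.60 ± 0.24) and Btn1a1 led the falls. The adipocyte list mean was 3.27 in normal mammary gland, 1.18 in normal prostate and 0.97 in normal lung. That of milk and luminal genes was 2.05, 0.25 and 0.27 in the same order. The rule does not tell a change in tumor cells from such differences between normal tissues. Lung tumors had 133 specific genes, 26 higher and 107 lower. The rule compares the 3 epithelial sites only, and Clu (1.88 ± 0.35), the largest rise among them, rose in seminal vesicle tumors too. Others higher in lung are Lypd6b (1.72 ± 0.29), Pex5l (1.70 ± 0.18), Nop58 (1.52 ± 0.13) and the developmental regulators Eya2 (1.39 ± 0.27) and Eya1 (1.33 ± 0.25). Ankrd1 (-2.50 ± 0.34), Pfkfb4 (-1.96 ± 0.31), the growth factor receptor Pdgfra (-1.91 ± 0.34), Loxl3 (-1.91 ± 0.19), Fibin (-1.91 ± 0.14) and Igfbp4 (-1.90 ± 0.22) were lower. The higher share of lung-specific genes was 19.5%, and 35.8% under quantile normalization. Prostate tumors had 762 specific genes, 348 higher and 414 lower. Elavl4, Marcksl1, Dcx (3.28 ± 0.22), Gap43, Nsg1 and Cwf19l2 (2.66 ± 0.18) led the rises, and Dcpp3 with the muscle genes Tnnc2, Mb, Mylpf, Tnni2 and Tpm2 led the falls. The same limit holds for the muscle genes, whose list mean was 3.96 in normal prostate, 1.27 in normal mammary gland and 0.38 in normal lung. In the study's rule at feature level the numbers were 220 for lung and 997 for prostate, where the series text states 220 and 999.

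The direct arrays asked how tumors of 8 mammary models differ from normal gland. In all 8 models adipocyte and skeletal muscle markers fell, and these 2 lists passed with an estimated correlation in each. Of 14 muscle genes 14 fell in the Brca1 model, 12 in C3(1) Tag, 10 in MMTV-ras and MMTV-PyMT and 11 in the other models. Adjusted over the list alone these were 14 genes in the Brca1 model, 12 in C3(1) Tag, p53 null and p53 floxed, 10 in MMTV-ras and 11 in MMTV-her2/neu, MMTV-myc and MMTV-PyMT. On the reference arrays the muscle list did not pass in C3(1) Tag mammary tumors. Its mean there was 1.27 ± 1.69 (SD, n = 4) in normal gland and 1.05 ± 0.87 (n = 4) in tumors. Muscle in the normal gland of the direct arrays and a change in tumors cannot be told apart. Of 12 adipocyte markers between 9 and 12 fell per model, and the same range holds adjusted over the list alone. The fatty acid binding protein Fabp4 stood at -5.34 ± 0.34 in p53 null, -6.04 ± 0.38 in p53 floxed, -4.06 ± 0.38 in C3(1) Tag, -5.50 ± 0.44 in MMTV-her2/neu, -4.16 ± 0.44 in MMTV-myc, -4.77 ± 0.38 in MMTV-ras and -5.27 ± 0.38 in MMTV-PyMT tumors. In the Brca1 model Lpl (-5.52 ± 0.41), Pvalb (-5.39 ± 0.36) and Tnnc2 (-5.66 ± 0.48) fell most. Lcn2, an iron-binding acute phase protein, rose in p53 null (4.29 ± 0.64), MMTV-her2/neu (4.45 ± 0.72), MMTV-myc (5.24 ± 0.72), MMTV-ras (4.71 ± 0.72) and MMTV-PyMT tumors (4.27 ± 0.64). Aqp5, a water channel, rose in MMTV-her2/neu (5.00 ± 0.47), MMTV-myc (3.89 ± 0.53) and MMTV-ras tumors (4.05 ± 0.47). The collagen gene Col9a1 rose in MMTV-her2/neu (4.58 ± 0.41) and MMTV-myc (4.64 ± 0.46), and Chil1 in MMTV-ras (4.36 ± 0.43) and MMTV-PyMT (3.38 ± 0.43). The galectin Lgals3 rose in p53 floxed (3.15 ± 0.42), Brca1 (3.46 ± 0.37) and C3(1) Tag tumors (3.55 ± 0.37), and Sdc1 in the Brca1 model (3.03 ± 0.28) and C3(1) Tag (3.15 ± 0.28). Cd44 (3.35 ± 0.37) and S100a9 (3.31 ± 0.47) rose in p53 floxed tumors and Ly6d (3.15 ± 0.49) in C3(1) Tag tumors.

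Among the genes named throughout, Top2a rose in the Brca1 model (1.80 ± 0.35), C3(1) Tag (1.99 ± 0.40) and p53 floxed tumors (1.21 ± 0.40), where the call was lost without p53 floxed array 1 (1.22) or 3 (0.61). Mki67 rose in C3(1) Tag (1.03 ± 0.18). Brca1 mRNA rose in the Brca1 floxed model (1.24 ± 0.22) and in C3(1) Tag (0.76 ± 0.22), where it was lost without array 2 (0.56). The rise in the Brca1 floxed model goes against its label. It rests on 1 feature, and where that clone lies relative to the deleted part of the gene is not known. Ccnd1 rose in the Brca1 model (2.23 ± 0.28), MMTV-myc (2.16 ± 0.31), MMTV-her2/neu (1.83 ± 0.28), p53 floxed (1.70 ± 0.31) and MMTV-ras (1.61 ± 0.36), and stood at -0.12 ± 0.31 in C3(1) Tag. Rb1 fell by 1.12 ± 0.20 in the Brca1 model and rose by 0.65 ± 0.18 in C3(1) Tag. Mitosis genes rose in 24 of 28 cases in C3(1) Tag, 23 in the Brca1 model, 11 in p53 floxed and 10 in p53 null tumors, against 6 in MMTV-her2/neu and 5 in MMTV-PyMT. With an estimated correlation the adjusted p was 0.208, 0.247, 0.409, 0.378, 0.597 and 0.758, and adjusted over the list alone the counts were 24, 23, 14, 12, 6 and 5. After median centring 24, 20, 19, 13, 6 and 9 mitosis genes rose and under quantile normalization 24, 21, 18, 19, 10 and 13, and the difference between these counts was not tested. In MMTV-myc 12 mitosis genes rose and in MMTV-ras 7, where the list did not pass (adjusted p = 0.0912 and 0.137). Replication genes rose in 18 of 21 cases in C3(1) Tag, 17 in the Brca1 model, 11 in MMTV-myc, 8 in p53 floxed, 3 in p53 null and 2 in MMTV-her2/neu tumors. As lists these passed, with an adjusted p of 0.232, 0.38, 0.728, 0.409, 0.686 and 0.597 with an estimated correlation. Adjusted over the list alone 19, 17, 11, 9, 3 and 2 rose, after median centring 15, 17, 5, 12, 3 and 4, and under quantile normalization 15, 15, 10, 14, 9 and 10. In MMTV-ras 7 and in MMTV-PyMT 3 replication genes rose, and the list did not pass (adjusted p = 0.205 for each). Of 5768 genes 830 passed in p53 null (344 higher), 1310 in p53 floxed (662 higher), 2708 in the Brca1 model (2011 higher), 2663 in C3(1) Tag (2413 higher), 1012 in MMTV-her2/neu (541 higher), 1357 in MMTV-myc (1200 higher), 1165 in MMTV-ras (993 higher) and 1220 in MMTV-PyMT (730 higher). Uncentred, the median of all genes lay at 0.36 in C3(1) Tag, 0.24 in the Brca1 model, 0.21 in MMTV-myc and 0.18 in MMTV-ras, and median centring took the higher share from 90.6% to 53.5% in C3(1) Tag, from 74.3% to 55.3% in the Brca1 model and from 85.2% to 52.8% in MMTV-ras. In MMTV-myc 705 genes were higher and 626 lower after centring. In p53 floxed tumors the share went from 50.5% to 61.9%, and to 72.3% under quantile normalization. Quantile normalization gave 2154 genes in p53 null (68.8% higher, against 41.4% before), 2249 in MMTV-her2/neu, 1937 in MMTV-ras and 2100 in MMTV-PyMT. Array weights gave 2190 in p53 null, 1622 in the Brca1 model and 2848 in MMTV-her2/neu, and fits of the groups compared alone gave 1400, 1613 and 2347 in these models and 697 in MMTV-myc. Single arrays moved the counts by over 1.5 times in p53 null (528 without array 2), p53 floxed (655 without array 3), MMTV-her2/neu (619 without array 1), MMTV-myc (767 without array 3), MMTV-ras (588 without array 3) and MMTV-PyMT tumors (730 without array 1).

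C3(1) Tag tumors were set against the mean of the 4 other FVB oncogene models. Ly6d (3.59 ± 0.56), the gap junction protein Gja1 (3.16 ± 0.28), S100a6 (2.80 ± 0.31), Lgals3 (2.69 ± 0.42), Anln (2.46 ± 0.36) and Sdc1 (2.18 ± 0.31) were higher. Aqp5 (-3.30 ± 0.53), Chil1 (-3.11 ± 0.48), Lcn2 (-3.08 ± 0.73), Col9a1 (-3.01 ± 0.46), Ano1 (-2.74 ± 0.44) and the casein Csn1s1 (-2.59 ± 0.55) were lower. Mitosis genes were higher in 21 of 28 cases, replication genes in 16 of 21 and chromatin genes in 5 of 9. With an estimated correlation the adjusted p was 0.226, 0.234 and 0.276. After median centring 12, 11 and 5 of them passed, and under quantile normalization 10, 10 and 4. Ribosomal protein genes were lower in 9 of 19 cases and luminal genes in 4 of 12 (adjusted p = 0.166 and 0.135 with an estimated correlation). Respiratory chain genes, endoplasmic reticulum genes and interferon-stimulated genes passed camera as lower lists with 1 of 16, 1 of 15 and 0 of 15 single genes passing, and with an estimated correlation their adjusted p was 0.276, 0.234 and 0.825. After median centring 4, 2 and 0 of their genes were lower, and under quantile normalization 4, 5 and 0. The mean of the interferon list was 0.04 as deposited, where all genes had a median of 0.26, and -0.21 and -0.27 under these scalings. They gave 12 lower ribosomal protein genes each, and 5 and 6 lower luminal genes. Adjusted over the list alone, 25 mitosis, 18 replication and 6 chromatin genes were higher, 10 ribosomal and 5 luminal genes were lower, and no gene of the other 3 lists passed. Mki67 (0.97 ± 0.20) was higher and Ccnd1 lower (-1.72 ± 0.34), and Top2a was higher (1.53 ± 0.44) except without C3(1) Tag array 1 (1.40), 2 (1.22) or 5 (1.18). Brca1 (0.58 ± 0.25), Rb1 (0.51 ± 0.20) and Myc (0.05 ± 0.20) did not pass. In all 1018 genes differed, 943 of them higher in C3(1) Tag. After median centring 674 differed, 59.9% of them higher against 92.6% before. Without C3(1) Tag array 5 the count was 395, and without array 2 it was 469.

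The 3 p53 and Brca1 models were also set against the 4 FVB oncogene models, with strain differing between the sets and no array run holding arrays of both. S100a6 (2.53 ± 0.22), Tnfrsf11b (2.29 ± 0.30), S100a9 (2.18 ± 0.34), Capza2 (2.18 ± 0.49), the matrix protein Tnc (2.07 ± 0.31) and Tes (2.06 ± 0.44) were higher. Chil1 (-3.31 ± 0.34), Pck1 (-2.60 ± 0.48), Gsn (-2.53 ± 0.26), the p53 target Ccng1 (-2.32 ± 0.22), Hey1 (-2.18 ± 0.24) and Myh2 (-2.15 ± 0.31) were lower, as was Rb1 (-0.81 ± 0.14). Mitosis genes were higher in 10 of 28 cases, replication genes in 5 of 21 and macrophage markers in 5 of 15, with an adjusted p of 0.381, 0.782 and 0.782 with an estimated correlation. Skeletal muscle genes were lower in 11 of 14 cases, adipocyte markers in 5 of 12 and respiratory chain genes in 3 of 16, with an adjusted p of 0.381, 0.782 and 0.896 with an estimated correlation. The direct ratios are over normal gland, so muscle in that gland can enter this difference. Adjusted over the list alone, 14 mitosis, 5 replication and 6 macrophage genes were higher, and 13 muscle, 6 adipocyte and 3 respiratory chain genes were lower. Median centring gave 17 mitosis genes higher. Under quantile normalization the mean of the adipocyte list moved from -0.79 to -0.01, with 4 genes higher and 2 lower, that of the muscle list from -1.29 to -0.31, with 3 genes lower, and that of the respiratory chain from -0.38 to -0.11, with 2 lower. Top2a (0.73 ± 0.29), Myc (0.34 ± 0.14), Mki67 (0.28 ± 0.14), Brca1 (0.14 ± 0.18) and Ccnd1 (-0.02 ± 0.23) did not pass. In all 1176 genes differed, 385 higher and 791 lower. After median centring 1674 differed, 49.5% of them higher against 32.7% before. With array runs as a random block 742 differed.

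A last comparison asked whether the shared SV40 genes move in other mammary tumors, with 79 of the 91 rising and 28 of the 32 falling genes measured on the direct arrays. The 91 rising genes hold 25 mitosis and 13 replication genes, so the score is in part a measure of cell division and not particular to SV40 antigen. The score was 2.55 ± 0.41 (SD, n = 5) in the Brca1 model, 2.06 ± 0.54 (n = 5) in C3(1) Tag, 1.99 ± 0.28 (n = 4) in p53 floxed and 1.61 ± 0.44 (n = 5) in p53 null tumors. In the oncogene models it was 1.09 ± 0.35 (MMTV-PyMT, n = 5), 1.05 ± 0.31 (MMTV-myc, n = 4), 1.02 ± 0.33 (MMTV-ras, n = 5) and 0.99 ± 0.16 (MMTV-her2/neu, n = 5). Over the 8 model means, the 4 models with SV40 antigen or with an engineered p53 or Brca1 gene exceeded the 4 oncogene models by 1.02 (exact permutation test, two-sided p = 0.0286, the smallest that 70 splits allow). The place of C3(1) Tag in this test is not independent, since the genes were chosen on arrays that include its mammary tumors. Without it, in a test chosen after the data were seen, the 3 p53 and Brca1 models exceeded the oncogene models by 1.01 (exact p = 0.0286, the smallest that 35 splits allow). C3(1) Tag exceeded MMTV-her2/neu by 1.07, MMTV-ras by 1.04, MMTV-myc by 1.01 and MMTV-PyMT by 0.97, with exact p of 0.00794, 0.0159, 0.0317 and 0.0238 and an adjusted p of 0.0556 for each over 7 comparisons, which did not pass. Against the p53 null, p53 floxed and Brca1 models C3(1) Tag differed by 0.45, 0.07 and -0.49 (exact p of 0.190, 0.825 and 0.159). The rising genes alone gave a difference of 0.51 with an exact p of 0.0571, and the falling genes alone 0.51 with an exact p of 0.0857. Unlike the score, which is unaffected by centring an array, these 2 parts depend on its level. With arrays centred the differences were 0.49 and 0.52, each with an exact p of 0.0286. The score also grows with the spread of log ratios on an array. Array SDs ran from 0.70 to 1.01 in the Brca1 model and from 0.71 to 0.82 in p53 floxed tumors. They ran from 0.61 to 0.79 in C3(1) Tag and from 0.52 to 0.67 in p53 null tumors. In MMTV-her2/neu and MMTV-ras the highest were 0.62 and 0.63, and in MMTV-myc and MMTV-PyMT 0.82 and 0.75. How far the score follows this spread was not tested. The falling genes include the adipocyte markers Fabp4, Lpl and Cd36. Over the 8 model means the score had a Pearson r of -0.770 with the mean of the adipocyte list, which was -1.73 in C3(1) Tag and -1.98 in MMTV-her2/neu, against the trend. With arrays centred the r was -0.864, and these means were -2.06 and -1.95, which goes with the trend. Without the genes of that list the difference was 0.98 (exact p = 0.0286), which leaves other genes of fat cells in the score. Centred parts and the score without adipocyte markers were chosen after the data were seen. The p53 and Brca1 models differ from the oncogene models in strain and share no array run with them, so model, strain and run cannot be told apart in their scores. The same choice of genes bears on each comparison of C3(1) Tag with a single model, whose score is not independent evidence.

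**Figure D3:**
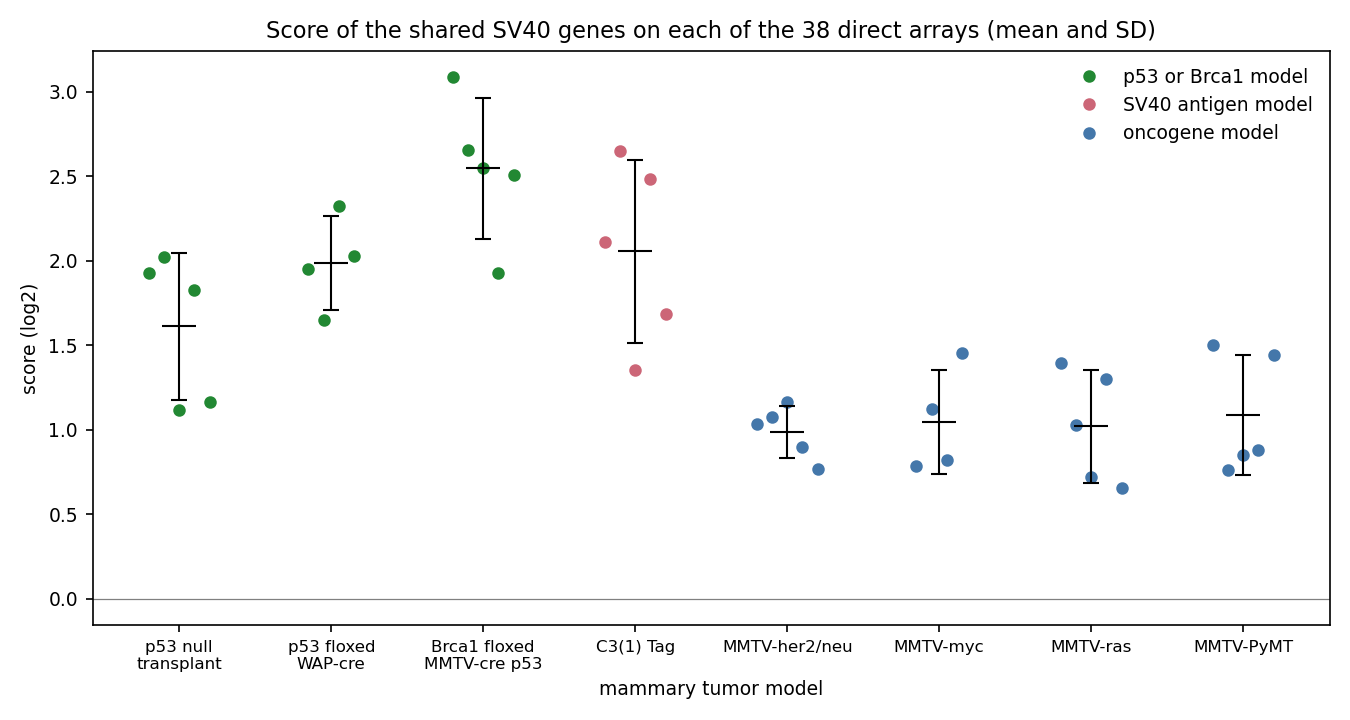
Score of the shared SV40 genes (y axis, log2) on each of the 38 direct arrays by mammary tumor model (x axis), with black bars for the model mean and SD. All 4 oncogene models have means between 0.99 and 1.09, and the other 4 models have means between 1.61 and 2.55.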

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

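The array checks and splits below were planned before the data were examined, while the tests of the 3 patterns weighed (muscle, neuroendocrine and C3(1) Tag) were all chosen after the result was seen. A check for 1 array far from the others of its group found 6 such groups among 80, where 4 would be expected by chance at a rate of 1 in 20. The number of features with a value stood apart in seminal vesicle tumor 6 (9504), mammary normal 4 (9368) and mammary tumor 4 (9244). The array median stood apart in lung normal 2 (-0.025132) and p53 floxed tumor 1 (0.17625). The mean of the skeletal muscle list stood apart in seminal vesicle tumor 2 (0.66837). No array was left out for this.

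Several results differ between groups of samples. The tumor change differed among the 4 sites for 5007 genes (1 of 100 splits of the same arrays, the real one included, gave as many, and the highest other gave 1051). These splits shuffled tumor and normal labels within each site, so they bear on any tumor change and not on a difference among sites. Between prostate and seminal vesicle the tumor change differed for 3156 genes (1 of 100, highest other 1588). C3(1) Tag differed from the 4 other FVB oncogene models in 1018 genes (1 of 100, highest other 80). The p53 and Brca1 models differed from the oncogene models in 1176 genes (1 of 100, highest other 41), with strain differing between the sets. For both model contrasts single arrays were shuffled over the models, so each split mixed models. Any difference between models makes the real split stand out, and arrays are not replicates of a set of models. Such splits therefore do not test the grouping of models. Prostate tumors had 762 specific genes (1 of 100, highest other 221). Mammary tumors had 206 and lung tumors 133, and here 2 of 100 splits gave as many, with highest others of 326 and 340. For these site-specific counts and for prostate against seminal vesicle, tumor arrays were shuffled over the sites compared, and normal arrays likewise. Each such split mixed tissues, and any difference between tissues widens the spread within its groups. These splits therefore do not test the difference of tumor changes between sites alone. 11 genes fell in the 3 epithelial tumors and rose in seminal vesicle tumors, and 1 with array runs as a fixed factor. For the tumor against normal counts the real split was the only 1 to reach its number in prostate (4157, 1 of 100, highest other 3636), seminal vesicle (2943, 1 of 100, highest other 1990), mammary gland (2485, 1 of 35, highest other 691) and lung (2474, 1 of 35, highest other 662). The seminal vesicle split also carries the array runs, with normal arrays in run 3 and tumor arrays in runs 4 to 6, and with runs as a fixed factor 884 genes passed. That fit links run 3 to other runs through 1 mammary tumor array only. For the 123 shared genes the real split was 1 of 100, with a highest other of 0. These splits shuffled tumor and normal labels within each site. They bear on a tumor change at each site and not on whether the sites share it.

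The fall of skeletal muscle and respiratory chain genes in prostate tumors was weighed with 4 tests, all chosen after the fall was seen. All 14 of 14 muscle genes were at least 2-fold higher in normal prostate than in the mean of normal seminal vesicle and lung, so muscle tissue taken with normal prostate may account for their fall. Within array run 1 the mean change of the muscle list was -3.954, which rests on 1 tumor array and decides nothing alone, but normal prostate exceeded normal lung by 3.6535 there (3 arrays each), which argues against the level of that run. With the muscle list mean as a covariate the mean change of respiratory chain genes moved from -0.488 to -0.11045 and the falls from 15 to 2, while the median standard error of a gene rose from 0.129 to 0.253. The slope of the covariate is fitted within groups. There the muscle mean varied most in mammary gland (SD 1.69 in normal, 0.87 in tumor) and less in prostate (0.37 and 0.08). The shift in prostate thus rests largely on mammary arrays and does not decide on muscle in normal prostate. The covariate sets the mean change of the muscle list itself to 0 by construction, says nothing on that list, and also moved the means of adipocyte (-1.33 to -0.53), smooth muscle (-1.89 to -0.81) and ribosomal protein genes (0.56 to 0.24).

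The rise of neuroendocrine genes in prostate but not in seminal vesicle tumors was weighed with 2 tests, both chosen after the rise was seen. Within array run 6, which holds tumors of both sites, prostate exceeded seminal vesicle by 1.4065 in the mean of the list, so a run difference is unlikely to be the reason. Glia and Schwann cell genes had a median change of -0.66231 in prostate tumors, with 7 of 9 measured genes lower and 0 higher (Apod -2.64 ± 0.18, Mbp -1.35 ± 0.22). More nerve with its glia in tumor than in normal samples is thus an unlikely source. The fall is relative to normal prostate, which may hold other tissue, and does not show that nerve is absent from tumors. The list was chosen for glia, so it does not test nerve cell bodies. With the muscle list mean as a covariate the mean change of the neuroendocrine list was 1.51 and 8 of 11 genes rose. Neuroendocrine tumor cells remain a possible reading, which RNA of whole tissue does not settle.

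The excess of genes higher in C3(1) Tag than in the oncogene models was weighed with 1 test chosen after it was seen. After median centring 59.941% of the genes that differ were higher, against 92.6% before. Centring itself took the median of all genes from 0.261 to 0.0121, so this fall decides nothing on the source of the excess. Array level and a change of most genes in C3(1) Tag tumors cannot be told apart here, since the files hold no control features.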

How the results depend on the processing

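Values within array run 1, the muscle covariate, the score test without C3(1) Tag, the score without adipocyte markers, the centred parts of the score and the shared genes of seminal vesicle under other settings were chosen after the data were seen. Counts of genes moved with the rule and, in the comparisons given here, with scaling, array weights, array runs and the groups that enter the fit, while a trended and robust variance model moved none; the cause was not tested unless stated. Fewer genes pass by construction where a fold change or the stricter rule of the study is asked. Under the study's rule, at feature level, the counts were 1483 in prostate, 283 in seminal vesicle, 644 in mammary gland, 617 in lung, 1475 between prostate and seminal vesicle, 2633 among the 4 sites and 220 specific to lung. On the direct arrays they were 367 in p53 null, 562 in p53 floxed, 986 in the Brca1 model, 1106 in C3(1) Tag, 333 in MMTV-her2/neu, 434 in MMTV-myc, 297 in MMTV-ras, 450 in MMTV-PyMT, 238 for C3(1) Tag against the oncogene models and 219 for the p53 and Brca1 models against them. With a 2-fold change asked as well they were, in the same order, 1159, 225, 520, 480, 1198 and 2228 on the reference arrays, and 321, 563, 807, 826, 319, 446, 284, 368, 219 and 193 on the direct arrays. Without a fold threshold 670 genes were shared, and 328 were specific to mammary gland, 268 to lung and 1280 to prostate. Quantile normalization gave 1629 in seminal vesicle, 2154 in p53 null, 2249 in MMTV-her2/neu, 1937 in MMTV-ras, 2100 in MMTV-PyMT, 639 for the C3(1) Tag contrast and 1768 for the p53 and Brca1 contrast, and median centring gave 674 for the C3(1) Tag contrast. With only genes that hold every value the direct counts were 351, 561, 1242, 1059, 458, 617, 488, 565, 350 and 548. Fits of only the groups compared gave 1400 in p53 null, 1613 in the Brca1 model, 2347 in MMTV-her2/neu and 697 in MMTV-myc, and array weights gave 2190 in p53 null, 1622 in the Brca1 model and 2848 in MMTV-her2/neu. Array runs as a fixed factor gave 884 in seminal vesicle and 1797 between prostate and seminal vesicle, where 1 mammary tumor array alone links normal seminal vesicle to other runs. Runs as a random block gave 494 in p53 null, 570 in p53 floxed and 742 for the p53 and Brca1 contrast. The skeletal muscle covariate, added after the data were seen, gave 1840 in prostate and 1535 between prostate and seminal vesicle. With an estimated correlation 37 list results passed, against 156 of 395. Fry kept fewer lists in the contrasts between models, 3 of 8 for C3(1) Tag and 3 of 6 for the p53 and Brca1 models. It also kept 8 of 10 in p53 null, 7 of 8 in the Brca1 model, 7 of 10 in C3(1) Tag, 10 of 13 in MMTV-her2/neu, 7 of 8 in MMTV-myc and 6 of 10 in MMTV-ras, and all lists in the other comparisons. With only genes that hold every value 3 of 10 lists were kept in p53 null, 10 of 15 in p53 floxed, 5 of 8 in the Brca1 model, 5 of 10 in C3(1) Tag, 7 of 13 in MMTV-her2/neu, 3 of 8 in MMTV-myc, 6 of 10 in MMTV-ras, 3 of 6 in MMTV-PyMT, 6 of 8 and 3 of 6 in the 2 contrasts between models, and 14 of 15 between prostate and seminal vesicle. All lists were kept in the other comparisons. The score difference was 0.51 with only the rising genes and 0.51 with only the falling genes, and neither passed. With arrays centred these were 0.49 and 0.52, and without C3(1) Tag the difference was 1.01 and without adipocyte markers 0.98, each with an exact p of 0.0286. Of the 91 shared rising genes 73 rose in seminal vesicle, 72 after median centring, 38 under quantile normalization and 34 with array runs as a fixed factor. Of the 32 falling genes 11, 11, 7 and 1 rose there. The files hold ratios only, so the limit set by signal over background is not analysed here.

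Replicate numbers as a block, a pairing that the arrays gave no sign of (0 of 4 reference group pairs and 0 of 28 direct group pairs), gave 4107 genes in prostate, 2896 in seminal vesicle, 2521 in mammary gland and 2521 in lung, and no result moved. With each array left out in turn the counts ran from 528 to 752 in p53 null, 655 to 1073 in p53 floxed, 619 to 751 in MMTV-her2/neu, 767 to 1423 in MMTV-myc, 588 to 1170 in MMTV-ras, 730 to 1161 in MMTV-PyMT and 395 to 1238 for the C3(1) Tag contrast. The 4 tumor against normal counts of the reference arrays stayed between 3919 and 4119, 2545 and 2999, 2192 and 2451, and 2186 and 2321. Of 4574 values of named genes with an array left out, 4507 kept their call, 47 lost it, 20 gained it and 0 turned.

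Named genes turned direction under 2 settings, both added after the data were seen. With the muscle covariate in prostate Myh1 came to 0.03636, Tnni2 to 0.8678, Tnnc2 to 1.296 and Serpinb5 to 0.05749, and Tnnc2 between prostate and seminal vesicle to 1.155, none of which passed. For the muscle genes that follows from the covariate, which sets the mean of their list to 0. Within array run 1 Myc came to -1.084 and Pdgfra to 1.162 in prostate. Both rest on 1 tumor array, with the spread taken from other arrays of that run, and decide no direction.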

Other observations

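Regulators of the G1 to S transition and p53 targets did not move as lists in most sites, yet single members moved far. Except for Ccng1, which was named by the rule in other comparisons, the genes in this paragraph and the next lie outside the naming rule. All were chosen here after their values were seen. Ccnd2, a D-type cyclin, fell in prostate (-1.41 ± 0.22), mammary (-1.77 ± 0.23) and lung tumors (-1.29 ± 0.23) and did not pass in seminal vesicle tumors (0.49 ± 0.21). Rbl1, the Rb relative p107, rose in prostate (1.17 ± 0.12), seminal vesicle (0.40 ± 0.11), mammary (1.27 ± 0.12) and lung tumors (1.80 ± 0.12). Cdk4 rose in prostate (2.19 ± 0.17), seminal vesicle (0.83 ± 0.16) and lung tumors (0.83 ± 0.17) and did not pass in mammary tumors (0.07 ± 0.17). Among p53 targets Ccng1 fell by 3.03 ± 0.22 in prostate tumors and rose by 0.51 ± 0.21 in seminal vesicle tumors, and Phlda3 fell in prostate (-1.45 ± 0.16) and mammary tumors (-1.55 ± 0.16). Gadd45a rose in prostate tumors (2.12 ± 0.28), and Cdkn1a rose in prostate (0.66 ± 0.26), seminal vesicle (0.76 ± 0.25) and mammary tumors (0.80 ± 0.27) and fell in lung tumors (-0.96 ± 0.27).

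Ube2c, a ubiquitin-conjugating enzyme of mitosis, ran against its list in 3 of 4 sites. It fell in prostate (-0.43 ± 0.16), mammary (-0.90 ± 0.17) and lung tumors (-0.84 ± 0.17), and rose with its list in seminal vesicle tumors (0.51 ± 0.16). In prostate tumors the secretory and lineage genes moved both ways, with Tmprss2 at -2.52 ± 0.33 and Hoxb13 at 1.43 ± 0.37, and the prostate secretory list as a whole did not pass (2 of 10 rose, 6 fell, adjusted p = 0.0871). Krt5, a basal keratin, rose by 1.22 ± 0.17 in seminal vesicle tumors and fell by 0.61 ± 0.17 in prostate tumors.

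Within 1 gene, features often went opposite ways in the C57BL/6 tissues (45 of 278 genes in prostate and 40 of 130 in seminal vesicle, against 5 of 128 in mammary gland and 7 of 129 in lung). The reason was not tested.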
